A study of Mus musculus with 16 samples.

How the data were processed

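RNA from 16 libraries of a mouse collecting duct cell line was measured in 4 groups of 4, passage 4 and passage 7 each with and without DOX, as the sample titles give them. Per the labels' protocols, the authors selected poly(A) RNA from total RNA, made strand-marking libraries, sequenced 2 reads of 75 bp per fragment and aligned them with STAR 2.6.0c to GRCm38.p6. The authors deposited a table of raw counts per gene and a table of TPM values, both with Ensembl gene identifiers and 1 column per library. The counts are whole numbers, 9937504 to 17188295 per library. Which tool counted the reads, with which annotation release and strand setting, and how the TPM values were made is not given in the sources used here. Gene symbols, positions and biotypes were matched by identifier to the GRCm38 annotation for all 55536 genes.

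All results rest on the counts as deposited. Genes were kept by edgeR's filterByExpr (15316 of 55536; 25677 genes had no count in any library), libraries were scaled by TMM, and all 16 were fitted together with 1 mean per group and 12 residual degrees of freedom by edgeR 4.0.16's robust quasi-likelihood fit in R 4.3.3. The contrasts were DOX at passage 4, DOX at passage 7, their mean, their difference, and passage without and with DOX. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. CPM values are TMM-scaled, and the filter removed 40220 genes, which were not tested. Pkd2 was also tested by an exact 2-sided permutation test of CPM, 4 against 4, whose smallest possible p is 0.0286.

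Before the data were examined, 36 gene lists with 825 different symbols were fixed, all of which were found in the table. The 32 lists with at least 5 tested members were tested by camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists. Proximal tubule, loop and distal tubule, endothelial and leukocyte markers had too few tested members for a list test. The genes named in the text follow a rule also fixed before the data were examined. It took, for DOX at each passage and for passage without DOX, the 10 genes in each direction with the largest change among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. It also took the 5 genes in each direction with the smallest adjusted p for the difference of responses, the 10 in each direction changed at both passages with the smallest adjusted p, and up to 4 members of a list by adjusted p, with further members where they show its spread; those further members were picked after their values were seen. Genes without a proper symbol were passed over, and Pkd2 and Pkd1 were always reported. The genes named for the difference between replicates were chosen after their values were seen. A few genes that the rule would name are left out of the text because they are withheld for evaluation.

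Libraries of the same replicate number in different groups deviated together from their group means (correlations 0.18 to 0.37), so the numbers were treated as pairing the libraries, and a fit with replicate number as a block stands beside a result where it changed a call or moved a count by more than 1.5 times. The pairing follows replicates 1 and 2 against 3 and 4: correlations were 0.18 to 0.39 within these pairs and -0.34 to -0.18 between them, and 8 of 16 libraries correlated best with their own number. Libraries of the same number thus stood no closer than others of their pair. The values show the pairs and not a pairing by single number, so the block is finer than what they show. The main fit holds no block. No replicates were duplicates: the chi-square per degree of freedom between replicates was 1.87 to 4.65 within a pair and 10.4 to 19.0 between pairs. With the replicate pair as a term the biological coefficient of variation was 6%, against 10% without.

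The deposited TPM columns were compared with the counts by correlation over 8130 genes. Of 16 headers, 4 matched the count column of the same name best and 12 that of another group (best correlation 1.000, next best at most 0.927). Pkd2 fits the DOX labels of the count headers and not those of the TPM headers, so no TPM value is reported as a result, and the TPM table serves only as an alternative with its columns as headed.

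The steps were tested on counts simulated from the real means and library sizes with 200 genes changed and a list of 25 others shifted together, whose members also count among the calls. For DOX at passage 4, over 15150 genes, the main test recovered 22% of genes changed 1.25-fold, 77.6% of those changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 4-fold, and 9 of 161 calls (5.59%) were false. For DOX at passage 7 and passage without DOX, where nothing was changed, edgeR's test made 0 calls after adjustment. A shifted list had a camera p of 1e-21 (6.6e-06 with an estimated correlation) and an unchanged list 0.99. The simulated genes were drawn independently and without a replicate-pair effect. None of these values therefore tests the gene or list calls under correlated genes or the pairing seen in the data.

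The alternatives were DESeq2's size factors, total counts, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the compared groups alone, the TPM values on the log2 scale with a pseudocount of 1 or 0.1 by limma (genes with a TPM of at least 1 in 4 libraries), the replicate block and each library left out in turn. A term for the replicate pair, and each pair of replicates alone, were added after seeing the data, as was the cystic disease list without Pkd2.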

Results

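RNA was measured in an inner medullary collecting duct cell line, an epithelium of the last stretch of the mouse kidney tubule, made from a mouse in which doxycycline (DOX) induces loss of Pkd2. Pkd2 encodes polycystin-2, a cation channel of the primary cilium and the endoplasmic reticulum that is mutated in autosomal dominant polycystic kidney disease. Cells of passage 4 and of passage 7 were kept for 10 days on filters, and DOX at 2 ug/mL was present for 6 days or left out. The 16 libraries form 4 groups of 4, and the question named for the series is how transcripts respond early to the loss of Pkd2. Total counts ranged from 9937504 (passage 7 without DOX, replicate 4) to 17188295 (passage 4 with DOX, replicate 2). Of 55536 listed genes 15316 were tested. The titles call the cells of all 16 libraries Pkd2 knockout cells, while the genotype label is wild type for the 8 without DOX and knockout for the 8 with it. DOX and the knockout were therefore compared as one. No label says that the 4 replicates of a group are separate cultures, so the p-values measure only the spread between these samples.

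Pkd2 itself (chromosome 5, 104459450 to 104505819, GRCm38) fell with DOX at both passages, and all 8 libraries with DOX lay below all 8 without. Its mean at passage 4 was 140 ± 4.24 CPM (counts scaled to library size; SD, n = 4) without DOX and 52.7 ± 3.98 with DOX, a log2 fold change of -1.41 (SE 0.08) that left 37.6% of the level without DOX. At passage 7 the means were 185 ± 1.40 and 56.7 ± 8.07 CPM, a log2 fold change of -1.71 (SE 0.08) that left 30.6%. The adjusted p-values were 8.8e-10 and 4.3e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The exact 2-sided permutation p was 0.0286 at each passage, the smallest that the 70 arrangements of 4 against 4 can give. The response did not pass the test of a difference between passages (-0.30, SE 0.11, adjusted p = 0.26). Pkd1, which encodes the partner protein polycystin-1, rose at passage 4 by 0.25 on the log2 scale (SE 0.08, adjusted p = 0.037), and its value at passage 7 was 0.05 (SE 0.08, adjusted p = 0.72). The counts cover the whole of each gene, so reads from parts of Pkd2 that remain after the deletion are included. The p-values of Pkd2 take the DOX labels of the count headers as given. Those labels differ from the TPM headers and were preferred because of Pkd2, so Pkd2 is no separate check of them.

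**Figure D1:**
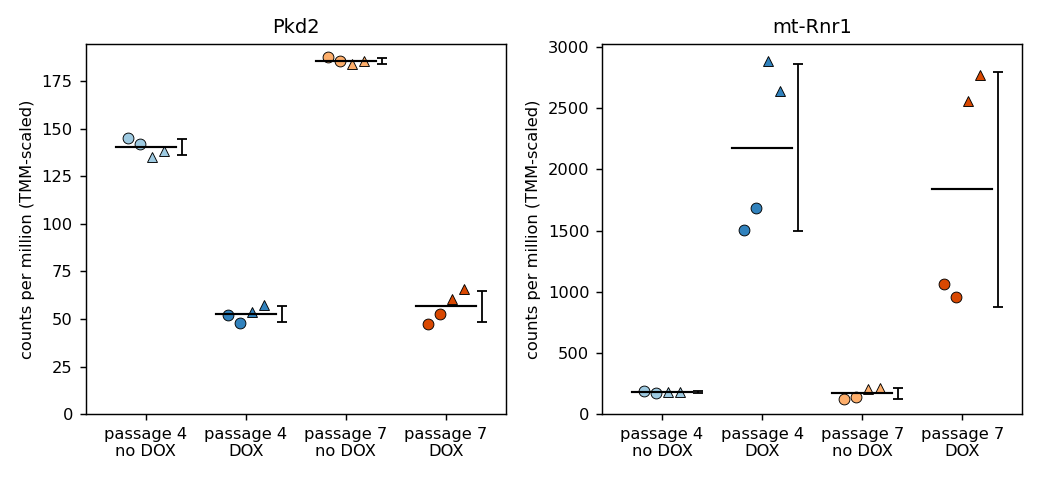
Pkd2 and the mitochondrial ribosomal RNA gene mt-Rnr1 in CPM in each of the 16 libraries, by group; circles are replicates 1 and 2, triangles replicates 3 and 4, lines the group means and bars 1 SD. The 8 libraries with DOX lie between 47.6 and 65.9 CPM for Pkd2 and between 956 and 2884 CPM for mt-Rnr1.

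The libraries of each group fell into 2 pairs, replicates 1 and 2 against replicates 3 and 4, in all 4 groups. The first principal component (38.2% of the variance) parted the passages and, within each, the DOX states, the second (21.7%) the DOX states, and the third (11.7%) replicates 1 and 2 from replicates 3 and 4. Between the pairs, 2673 genes were higher and 2984 lower in replicates 3 and 4 with group held constant. Among those genes were the cold-inducible RNA-binding protein gene Cirbp (log2 difference 0.91), the metallothionein gene Mt2 (0.92) and the interferon-induced GTPase gene Gbp2 (-0.96). The mitochondrial DNA-encoded subunits were higher in replicates 3 and 4 as a list (median log2 difference 0.66, camera adjusted p = 7.5e-18, and adjusted p = 0.042 with an estimated correlation). Some lists that are reported below for DOX or passage also differed between the pairs. Hypoxia targets (median -0.46), glycolysis genes (-0.38) and the interferon response (-0.24) were lower in replicates 3 and 4 by camera, each with adjusted p = 0.26 with an estimated correlation. Cell cycle genes were lower too (-0.26) and ATF4 targets higher (0.12), with adjusted p = 0.65 and 0.53 with an estimated correlation. Each group holds both pairs. Across all tested genes, the log2 fold changes from replicates 1 and 2 and from replicates 3 and 4 correlated with a Pearson r of 0.640 to 0.789 for the DOX and passage comparisons, and of 0.295 for the difference of responses.

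**Figure D2:**
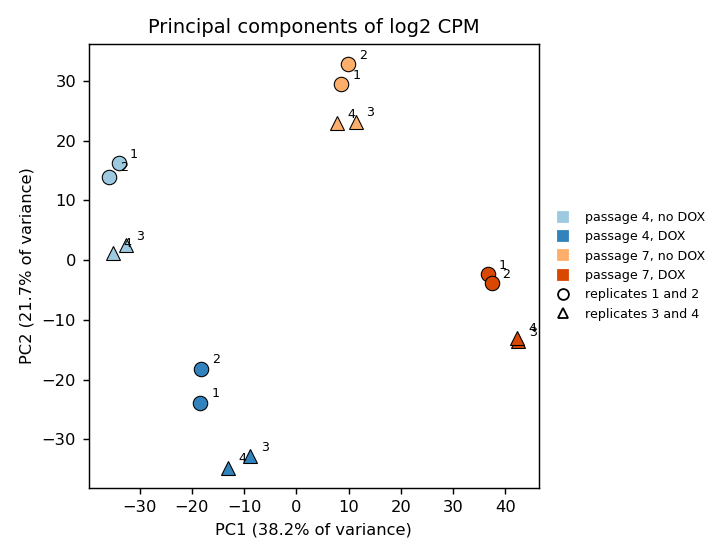
Principal components 1 and 2 of log2 CPM over the 15316 tested genes, 1 point per library, with colours for the 4 groups and replicate numbers beside the points. The circles (replicates 1 and 2) and triangles (replicates 3 and 4) separate within every group.

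Averaged over the passages, cells with DOX raised transcripts of the amino acid and mitochondrial stress response that ATF4 drives. They lowered transcripts of cholesterol synthesis. Counts of mitochondrial ribosomal RNA in these poly(A)-selected libraries rose as well. Ddit3, the stress transcription factor CHOP, rose by 1.59 on the log2 scale (SE 0.07), Atf5, a transcription factor of the mitochondrial stress response, by 0.93 (SE 0.04) and the tryptophanyl-tRNA synthetase gene Wars by 1.13 (SE 0.04). Insig1, a regulator of sterol sensing, fell by 0.94 (SE 0.08). With 8 libraries in each arm, 2401 genes rose and 2547 fell at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), of which 178 and 236 changed at least 2-fold.

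Of 30 tested ATF4 targets, 26 rose over all genes tested, 27 rose adjusted over the list alone, and Atf3, Ddit4, Gdf15 and Vldlr did not pass over all genes (median log2 fold change of the list 0.65). The members that rose include the serine and one-carbon enzymes Psat1 (0.86), Shmt2 (1.04) and Mthfd2 (0.77), asparagine synthetase Asns (0.80), the pseudokinase gene Trib3 (1.81) and Atf4 itself (0.57). The camera adjusted p of the list was 4.4e-46, and 0.0082 with an estimated correlation (0.053 with the replicate block added as well). At passage 4 alone 24 members rose, 25 adjusted over the list alone. The camera adjusted p there was 0.049 with an estimated correlation, and 0.075 with the replicate block added as well. At passage 7 alone 25 rose (27 adjusted over the list alone; adjusted p = 0.0060 with an estimated correlation). Of 15 mitochondrial chaperones and proteases, 9 rose and 1 fell (10 and 1 adjusted over the list alone), led by the matrix protease Lonp1 (1.02), the chaperones Hspa9 (0.75) and Hspd1 (0.26) and the co-chaperone Dnaja3 (0.42). Its camera adjusted p was 3.3e-05 (adjusted p = 0.15 with an estimated correlation). The 22 ER stress genes moved both ways, with 5 higher and 7 lower (6 and 8 adjusted over the list alone), a median of -0.07 and no call by camera (adjusted p = 0.99). The sensor gene Atf6 (0.35) and Sel1l (0.31), of ER-associated degradation, rose, while the ER chaperone genes Calr (-0.30) and Pdia6 (-0.19) fell.

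Both ribosomal RNA genes of the mitochondrial genome rose with DOX. mt-Rnr1 (chromosome M, 70 to 1024), which encodes the 12S ribosomal RNA, was between 127 and 212 CPM in the 8 libraries without DOX and between 956 and 2884 in the 8 with it. Its log2 fold change was 3.50 (SE 0.26, adjusted p = 3.1e-07). mt-Rnr2, the 16S gene, rose by 2.47 (SE 0.24, adjusted p = 3.6e-06), and mt-Tq, the transfer RNA gene for glutamine, by 5.62 (SE 0.63). Of 9 tested mitochondrial transfer RNA genes 6 rose and 1 fell. Of 13 listed mitochondrial DNA-encoded subunits 7 were tested. The others, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l, did not pass the filter, and the reason was not tested. The list result therefore covers only part of these subunits. Among the 7 tested, the complex I genes mt-Nd2 (1.57), mt-Nd4 (1.05) and mt-Nd6 (1.00) rose. The complex IV gene mt-Co1 fell by 0.51, and 3 did not pass (4 higher and 1 lower adjusted over the list alone). The median was 0.49 (camera adjusted p = 0.047, and adjusted p = 0.67 with an estimated correlation). Mitochondrial RNA made up 1.10% to 2.00% of the counts without DOX and 1.46% to 3.00% with it. In the libraries with DOX, mt-Rnr1 was higher in replicates 3 and 4 than in replicates 1 and 2, and its DOX response was 3.00 in the first pair of replicates and 3.80 in the second. The libraries were made from poly(A)-selected RNA, so a change in what that selection caught was not told apart from a change in RNA amount. Whether counting used the strand is not given in the sources used here, so mt-Tq, mt-Nd6 and other genes opposite another transcript are uncertain. Of 57 nuclear-encoded respiratory chain subunits 16 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.05), and camera did not call them (adjusted p = 0.088). At passage 7 alone 9 rose (6 adjusted over the list alone), and camera called the list higher (adjusted p = 0.046, and adjusted p = 0.82 with an estimated correlation).

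Of 25 targets of SREBP2, the transcription factor of cholesterol synthesis, 24 fell over all genes and adjusted over the list alone, and Ebp (0.13) was higher adjusted over the list alone. The median was -0.50 (camera adjusted p = 2.9e-22, and adjusted p = 0.0082 with an estimated correlation, or 0.078 with the replicate block added as well). The enzymes Sqle (-0.47) and Acat2 (-0.82) and the transcription factor gene Srebf2 (-0.48) were among them. Of 18 targets of NRF2, the regulator of antioxidant genes, 12 fell and 1 rose (14 and 2 adjusted over the list alone; median -0.29). The glutathione synthesis gene Gclm fell by 0.92 and the NADPH-producing enzyme gene Me1 fell by 0.38, while Slc7a11, a cystine transporter that is also an ATF4 target, rose by 0.94. Of 22 targets of the growth regulator YAP, 12 fell and 5 rose (13 and 5 adjusted over the list alone; median -0.22). Ankrd1 was at -1.27, Ccn1 at -1.31 and Wwc1 at -0.73, against Igfbp3 at 0.76. Of 25 NF-kB and chemokine genes 11 fell and 3 rose (12 and 3 adjusted over the list alone; median -0.25). The chemokine genes Cxcl5 (-2.19) and Ccl2 (-1.12), the growth factor gene Csf1 (-0.57) and the adhesion molecule gene Icam1 (-0.77) fell. Of 4 tested leukocyte markers, too few for a list test, 3 fell as well: Ptprc (-2.70), Cd68 (-0.85) and Csf1r (-0.68). Of 28 genes of the TGF-beta response and extracellular matrix 13 fell and 5 rose (13 and 6 adjusted over the list alone; median -0.22). The basement membrane collagen genes Col4a1 (-1.24) and Col4a2 (-1.35) and fibronectin, Fn1 (-0.87), fell, and the laminin gene Lama3 (0.78) rose. This list was lower at passage 4 (14 of 28 lower and 5 higher, 15 and 5 adjusted over the list alone; median -0.44; adjusted p = 4.9e-05, and adjusted p = 0.14 with an estimated correlation). At passage 7 camera did not call it (median -0.14, adjusted p = 0.83). The NRF2, YAP, NF-kB and TGF-beta lists were lower by camera, with adjusted p-values of 8.9e-05, 0.0013, 0.0029 and 0.035 in that order, and adjusted p = 0.25, 0.15, 0.33 and 0.45 with an estimated correlation.

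Genes of renal cystic disease went both ways: 4 of 25 rose and 7 fell (5 and 9 adjusted over the list alone; median -0.03; camera adjusted p = 0.047, lower, and adjusted p = 0.15 with an estimated correlation). That call rests on Pkd2, the gene deleted by design: without it the 24 other members had a camera adjusted p of 0.44 (0.17 at passage 7). Besides Pkd2, the RNA-binding protein gene Bicc1 fell by 1.12 (SE 0.05) and Pkhd1, which encodes the fibrocystin of recessive polycystic disease, fell by 0.66, while Glis2 (0.77) and Muc1 (0.45) rose. Of 20 tubular injury markers 9 fell and 4 rose (10 and 6 adjusted over the list alone; median -0.15). The camera adjusted p was 0.047 (adjusted p = 0.45 with an estimated correlation), and that call ended with replicate number as a block (adjusted p = 0.096). Havcr1, the kidney injury molecule KIM-1, fell by 2.01 and Spp1, osteopontin, fell by 0.91, while Krt20 rose by 0.73. Clock genes rose as a list, 7 of 16 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.32), led by Ciart (1.27), Nr1d1 (0.75) and Per2 (0.60). So did lysosome and autophagy genes under TFEB, 11 of 26 higher and 1 lower (12 and 1 adjusted over the list alone; median 0.10), including Hexa (0.41), Ctsa (0.31) and Lamp1 (0.27). Their camera adjusted p-values were 0.0039 and 0.0076, and adjusted p = 0.15 and 0.25 with an estimated correlation. In all, camera called 5 of 32 tested lists higher and 7 lower (4 and 5 with Pkd2 taken out of the cystic disease list), and with an estimated correlation only the ATF4 and SREBP2 lists held. With the replicate block added as well, their adjusted p-values were 0.053 and 0.078.

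**Figure D3:**
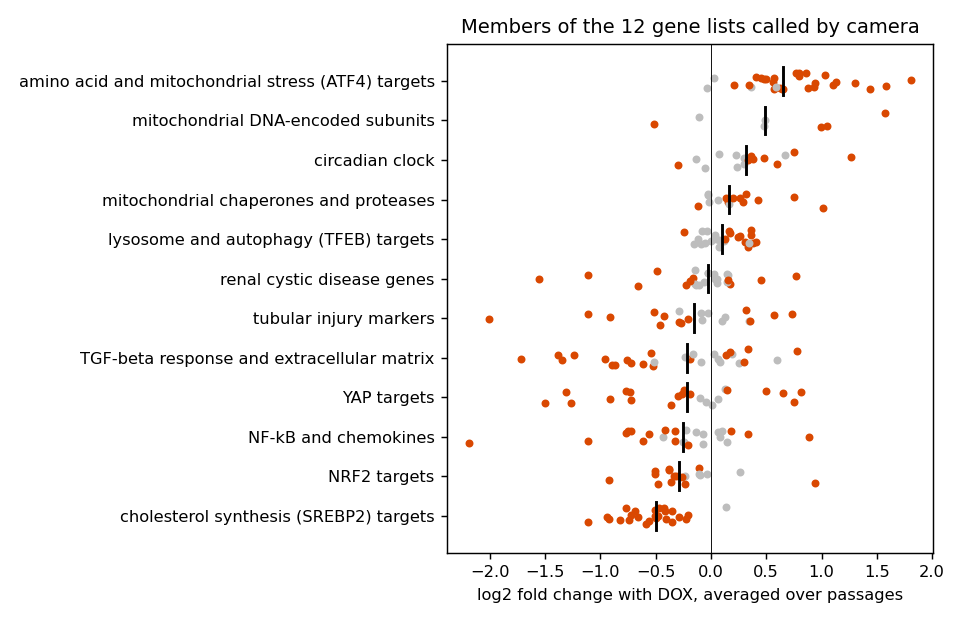
Log2 fold change with DOX, averaged over passages, of each tested member of the 12 gene lists that camera called; orange points passed an adjusted p of 0.05 over all genes, grey points did not, and black bars are list medians. The ATF4 list has the highest median (0.65) and the SREBP2 list the lowest (-0.50).

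Across the passages the DOX response was shared: 773 genes rose at both and 931 fell at both, where independent lists of the same sizes would share 143 and 161, and 16 genes went opposite ways. The 2 comparisons have no library in common, and their log2 fold changes correlated across genes with a Pearson r of 0.697 and a Spearman rho of 0.595 (genes are not independent replicates). With replicate number as a block the shared genes numbered 1294 higher and 1467 lower. The genes that changed at both passages with the smallest adjusted p-values lay apart in every library: for all 20 named here the 4 libraries with DOX were wholly above or wholly below the 4 without at each passage. Such a separation has an exact p of 0.0286 for a single gene at 1 passage that was not chosen by its p-value, as these were. Among those that rose were Nupr1, a stress-induced nuclear protein gene (averaged log2 fold change 1.21, SE 0.04), the secreted protease gene Htra1 (1.51), the interferon-induced gene Oasl1 (1.13) and the mitochondrial inner membrane protein gene Ghitm (0.81). So were the annexin gene Anxa8 (1.79), the cationic amino acid transporter gene Slc7a3 (1.83) and Hgfac (0.70), besides Wars, Ddit3 and Atf5. Among those that fell were the chloride channel regulator gene Clca3b (-2.55, SE 0.09), the tensin gene Tns1 of focal adhesions (-2.09), the septin gene Sept4 (-1.82) and the ciliary doublecortin-domain gene Dcdc2a (-1.78). So were Lhfp (-1.35), the formin gene Fhod3 (-1.15) and Sytl2 (-1.15), besides Pkd2, Bicc1 and Ankrd1.

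**Figure D4:**
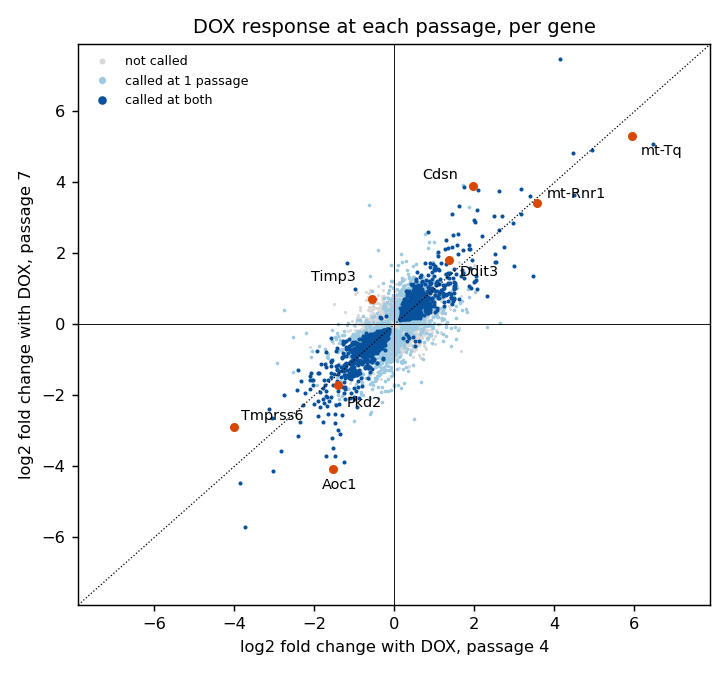
Log2 fold change with DOX at passage 4 (x axis) and passage 7 (y axis) for each of the 15316 tested genes; dark blue points passed an adjusted p of 0.05 at both passages, light blue points at 1, grey points at neither, and labelled genes are orange. Pkd2 lies at -1.41 and -1.71, mt-Rnr1 at 3.57 and 3.42, and Timp3 at -0.56 and 0.71.

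At passage 4, among genes of at least 5 CPM and besides the mitochondrial RNA genes, the largest rises with DOX were in Lrrc26, a regulatory subunit of potassium channels (2.98, SE 0.28), the teneurin gene Tenm4, the cytochrome P450 gene Cyp4b1 (2.04), Shank1 (2.01), the corneodesmosin gene Cdsn (1.96) and Dok7 (1.90). The largest falls were in the membrane protease gene Tmprss6 (-4.01, SE 0.34), Ggt7 (-3.06), the calcium sensor gene Ncald (-2.77), the calcineurin regulator gene Rcan2 (-2.43), Scube3 (-2.34), Fstl1 (-2.08) and the transcription factor gene Eya4 (-2.07), with Clca3b, Tns1 and Dcdc2a. In all, 1294 genes rose and 1393 fell (edgeR's quasi-likelihood test), 179 and 228 of them at least 2-fold. With replicate number as a block these counts were 2143 and 2291. Camera called 7 lists higher and 6 lower. The interferon response was higher here (5 of 39 members rose and 3 fell, the same adjusted over the list alone; median 0.16; camera adjusted p = 0.011, and adjusted p = 0.82 with an estimated correlation). With an estimated correlation 1 list held in each direction, ATF4 targets and SREBP2 targets (22 of 25 lower, 23 lower and 1 higher adjusted over the list alone; adjusted p = 0.0057 with an estimated correlation). With the replicate block added as well, both were at adjusted p = 0.075.

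At passage 7, by the same choice, Cdsn rose by 3.90 (SE 0.24), the transcription factor gene Dmrta1 by 3.76, the collagen gene Col26a1 by 3.11 and Pkhd1l1, a relative of the fibrocystin gene, by 3.10. So did the glycosyltransferase gene B4galnt2, by 3.05, Tenm4 by 3.04, Drp2 by 2.88 and the leukocyte tetraspanin gene Cd53 by 2.67. The largest falls were in the diamine oxidase gene Aoc1 (-4.07, SE 0.21), the retinoic acid-degrading enzyme gene Cyp26b1 (-3.49), Cxcl5 (-2.97) and Tmprss6 (-2.90). Next were Clca3b (-2.74), Inmt (-2.73), Ggt7 (-2.63), the activin-binding follistatin gene Fst (-2.58), Ggt1 (-2.33) and Sept4 (-2.25). In all, 1697 genes rose and 1769 fell, 210 and 294 of them at least 2-fold. Camera called 3 lists higher and 7 lower, 5 higher with replicate number as a block (the clock and mitochondrial DNA-encoded lists were added). With Pkd2 taken out of the cystic disease list, camera called 2 higher and 6 lower. With an estimated correlation the ATF4 list alone held; 0 lists were lower, against 2 at an unadjusted p under 0.05 and 12 by fry. The interferon response was lower here (1 of 39 rose and 8 fell, the same adjusted over the list alone; median -0.17; adjusted p = 0.040, and adjusted p = 0.82 with an estimated correlation).

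The size of the DOX response differed between the passages for 79 genes with a more positive and 104 with a more negative change at passage 7 (330 and 485 with replicate number as a block). Timp3, an inhibitor of matrix metalloproteinases, fell at passage 4 (-0.56) and rose at passage 7 (0.71), a difference of 1.26 (SE 0.13, adjusted p = 9.0e-05). Syn3, whose gene on the other strand encloses Timp3, followed it (difference 1.31) and is uncertain, since reads of the pair may have been shared. Cdh6 and Cdh13, which encode cadherins, rose at passage 4 (0.31 and 0.62) and fell at passage 7 (-0.48 and -0.46). Sat1, of polyamine breakdown, and Htra1 rose more at passage 7 (differences 0.72 and 0.82), Chpf, of chondroitin synthesis, rose less (-0.87), and Megf6 fell at passage 4 alone (-1.16 against 0.05). Aoc1 fell more at passage 7 (-2.53), and the kinase anchor gene Akap12 fell there (-0.68) and did not pass at passage 4 (-0.10). ATF4 targets had higher responses at passage 7 as a list (4 of 30 higher, 12 adjusted over the list alone; median 0.29; camera adjusted p = 1.9e-14, and adjusted p = 0.27 with an estimated correlation). So did genes of the TGF-beta response and extracellular matrix, with less of a fall there (4 of 28 higher, 7 adjusted over the list alone; median 0.16; camera adjusted p = 1.1e-07, and adjusted p = 0.27 with an estimated correlation). Interferon genes had lower responses there (no member of 39 passed over all genes and 4 were lower adjusted over the list alone; median -0.36; camera adjusted p = 1.4e-12, and adjusted p = 0.38 with an estimated correlation). The gene counts rest on few libraries: without replicate 1 of passage 4 with DOX they were 45 and 61.

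Without DOX, camera called the hypoxia, cell cycle and epithelial identity lists higher in cells of passage 7 than in cells of passage 4, and the interferon and NF-kB lists lower. None of these calls held with an estimated correlation (adjusted p = 0.54, 0.56, 0.066, 0.56 and 0.54 in that order). S100a14, a calcium-binding protein gene of epithelia, rose from 8.83 ± 0.943 to 65.7 ± 5.13 CPM (SD, n = 4; log2 fold change 2.89, SE 0.10), and the nuclear receptor gene Pparg from 1.29 ± 0.466 to 6.75 ± 1.33 CPM. Cldn19, a tight junction claudin of the thick ascending limb, fell from 27.1 ± 1.72 to 4.35 ± 0.695 CPM (log2 fold change -2.64, SE 0.13), and Erbb4, a receptor of the EGF receptor family, from 18.6 ± 2.12 to 1.99 ± 0.627 CPM. In all, 2187 genes rose and 1735 fell (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 389 and 205 of them at least 2-fold. Pkd2 rose by 0.40 (SE 0.08, adjusted p = 0.00069) and Pkd1 fell by 0.23 (SE 0.08, adjusted p = 0.045).

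Other large rises with passage were in the tensin gene Tns4 (3.58), the transcription factor gene Sp8 (3.19), the alcohol dehydrogenase gene Adh1 (3.00), Cyp26b1 (2.54) and the neighbouring genes Lrrc26 (2.32) and Grin1 (2.30). AC133103.1 and AC168977.1 rose as well (2.71 and 2.51); they lie on unplaced scaffolds and are uncertain, since near-identical copies may share reads. Other large falls were in Cadps2 (-3.54), of vesicle release, Thsd7b (-2.53), the transcription factor genes Pou3f3 (-2.46) and Tshz2 (-2.36), Il5ra (-2.28), the sodium-calcium exchanger gene Slc8a1 (-2.16) and the BMP antagonist gene Sostdc1 (-2.16).

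By list, 11 of 22 HIF targets rose with passage (16 adjusted over the list alone; median 0.68), including Ndrg1 (1.09), P4ha2 (1.18) and Hilpda (0.65), with camera adjusted p = 4.1e-06 and adjusted p = 0.54 with an estimated correlation. Of 35 cell cycle genes 14 rose (23 higher and 1 lower adjusted over the list alone; median 0.39), including Mcm7 (0.51), Mcm6 (0.41) and Rrm1 (0.54). Of 20 epithelial identity genes 9 rose (10 adjusted over the list alone; median 0.21), including the keratin gene Krt19 (0.51) and the junction genes Tjp3 (0.72) and Cldn3 (0.54). Their camera adjusted p-values were 1.3e-05 and 0.0021, and adjusted p = 0.56 and 0.066 with an estimated correlation. SREBP2 targets (10 of 25 higher, 11 adjusted over the list alone; Insig1 0.70, Cyp51 0.61) and clock genes (6 of 16, 7 adjusted over the list alone; Nr1d1 1.27) were higher too, with adjusted p = 0.54 and 0.37 with an estimated correlation. So were glycolysis genes (5 of 20, the same adjusted over the list alone; Pfkm 0.49) and adenylyl cyclases and phosphodiesterases (7 of 15 higher and 2 lower, 8 and 2 adjusted over the list alone; Adcy7 2.22, Pde8b -2.13), with adjusted p = 0.58 and 0.54 with an estimated correlation. Of 39 interferon response genes 14 fell and 1 rose (20 and 1 adjusted over the list alone; median -0.31; camera adjusted p = 4.2e-05, and adjusted p = 0.56 with an estimated correlation). Isg15 (-0.75) was among those that fell, and Oasl1 (0.91) rose. Of 25 NF-kB and chemokine genes 7 fell and 1 rose (the same adjusted over the list alone; median -0.18), including Ccl20 (-2.56) and Icam1 (-1.43), with camera adjusted p = 0.0089 and adjusted p = 0.54 with an estimated correlation. ER stress genes (9 of 22 lower and 1 higher, 11 and 1 adjusted over the list alone) and respiratory chain subunits (12 of 57 lower and 3 higher, the same adjusted over the list alone) were lower with adjusted p = 0.55 and 0.81 with an estimated correlation. Camera called 7 lists higher and 4 lower. With replicate number as a block 2 were lower, the ER stress and respiratory chain calls having ended at adjusted p = 0.076 and 0.069, and the adenylyl cyclase list at 0.056. With an estimated correlation camera called 0 lists, against 2 higher at an unadjusted p under 0.05 and 11 higher and 5 lower by fry.

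With DOX, 2806 genes were higher and 2417 lower at passage 7 than at passage 4, 479 and 346 of them at least 2-fold. S100a14 was again higher (2.79) and Cldn19 lower (-3.36), and Pkd1 fell by 0.44 (SE 0.08, adjusted p = 0.00047), while Pkd2 was at 0.11 (adjusted p = 0.31). Timp3, lower at passage 7 without DOX (-0.54), was higher there with it (0.73).

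The passage labels have no marker gene to check them by, and the column headers of the counts and of the deposited TPM values do not match: 4 of 16 TPM columns match the counts of the same header. The averaged DOX comparison uses the same libraries whichever passage they belong to, while the comparisons between passages and those at 1 passage rest on the count headers as given.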

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

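The tests of doxycycline itself, of ER stress and of the headers were chosen only after the results were seen; those of poly(A) carry-over, GC content, length and depth were written after the patterns were seen and before their own results were.

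Mitochondrial RNA and ATF4 target mRNAs rose together with DOX, mt-Rnr1 by 3.50 and the ATF4 list with a median of 0.65. Doxycycline itself, which inhibits mitochondrial translation, and the loss of Pkd2 cannot be told apart: 0 libraries with DOX lack the knockout label. Carry-over of RNA without a poly(A) tail is a candidate explanation. The 30 small RNA and histone genes had a median change of 0.15 (95% interval 0.04 to 0.32), with 3 higher and 2 lower. If the counts of these genes come from RNA without a tail, which was not tested, that argues against a carry-over of these kinds of RNA as large as the rise of mt-Rnr1. No nuclear ribosomal RNA was among them, so carry-over of longer RNA is left open. For ER stress as the source of the ATF4 targets, the ER stress list had a median of -0.07 (interval -0.14 to 0.08), with 5 higher and 7 lower. That argues against a shared rise of the genes on that list. The list has no gene in common with the ATF4 list, so it cannot tell whether ER stress acted through ATF4 alone.

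Replicates 1 and 2 differed from replicates 3 and 4 in 5657 genes. Of these, 87.8% remained with the same sign after the trend with GC content was taken out, 80.3% after that with transcript length and 88.3% after thinning to the lowest total, so none of the 3 is likely to be the source.

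The headers of the TPM table differ from those of the counts. Exchanged DOX labels among the count columns are argued against by Pkd2, which in 0 of the 8 count columns with DOX exceeded the lowest without. TPM columns under other libraries' headers account for the 12 that match the counts of another header best. Read in column order, each TPM column matches the count column at its own position, so the tables differ in the order of their headers. For the DOX labels, Pkd2 goes against the TPM headers. Each of the 4 TPM header groups held 1 replicate pair and 1 DOX state of the counts, which the differing order of the headers gives. An exchange of passage and replicate pair in the count headers would also go with that. Such an exchange would not by itself give the 8 TPM headers whose best match has another DOX state. Whether it is present as well cannot be told apart from the headers as given, since no value outside them marks passage, and the 5158 genes that differ between the pairs in a model with DOX and passage do not decide it.

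Regrouped libraries served as a check on chance. For DOX at passage 4 the real total of 2687 genes was the largest of 35 splits (highest other 1171, the split by replicate pairs). At passage 7 the total was 3466 (897), for passage without DOX 3922 (31) and with DOX 5223 (21), each the largest too. Averaged over passages 4948 genes were called (highest other of 100 splits 2121) and 1704 were shared (highest other 0). Among the 8 splits that part all pairs the highest others were 0, 0, 0, 0, 83 and 0 in that order. The real grouping thus gave the most calls each time. The other splits mix libraries of different groups, so a real change widens their spread and leaves few calls by construction. Since the replicates come in pairs that may not be separate cultures, chance between cultures was not excluded. For the difference of responses 6 of 100 splits had at least the real 183 genes (highest other 3864, also among the splits parting all pairs). Of the 5 others, 4 left the passage labels of the libraries with DOX whole or wholly exchanged and mixed those without DOX. Such splits keep the passage change in 1 DOX state alone and so make a difference by construction. They do not test chance for this result, which is left open. For the lists, 2 of 35 splits at passage 4 (real 13, highest other 13), 6 of 35 at passage 7 (10; 12), 5 of 35 for passage without DOX (11; 13) and 9 of 100 averaged (12; 13) were at least as large, so chance cannot be excluded. Among the splits parting all pairs the highest others were 13, 7, 8 and 9.

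Groups of 4 libraries were looked at for the named genes and for total counts, mitochondrial share and genes detected. Of these 316 groups, 14 held a library that lay far from the other 3, each for a named gene. For 4 independent libraries chance gives about 1 in 20. The libraries here fall into pairs, for which the rate was not worked out, so whether 14 is an excess is not known. At passage 4 with DOX, replicate 2 had 4.70 CPM of Shank1 (others 8.53 to 9.11), 289 of Tns1 (196 to 209), 13.3 of Tshz2 (9.03 to 9.33) and 87.8 of Oasl1 (105 to 107). At passage 4 without DOX, replicate 1 had 7.46 CPM of Eya4 (5.62 to 5.78), and replicate 2 had 29.6 of Cldn19 (25.9 to 26.4). There, replicate 3 had 457 of Ankrd1 (525 to 538), and replicate 4 had 0.781 of B4galnt2 (0.466 to 0.517) and 168 of Cdh6 (152 to 155). At passage 7 with DOX, replicate 1 had 11 CPM of Tns4 (7.11 to 7.68) and 257 of Hgfac (266 to 267), and replicate 4 had 5.97 of Scube3 (8.46 to 8.63). At passage 7 without DOX, replicate 2 had 3.80 CPM of Pou3f3 (2.61 to 2.73) and replicate 3 had 0.803 of Slc8a1 (1.4 to 1.5).

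The DOX response of some named genes differed between the passages by the direct test. The response at passage 7 minus that at passage 4 was positive for Cdsn (1.94), Col26a1 (1.66), Syn3 (1.31), Timp3 (1.26), Megf6 (1.21), Slc7a3 (1.09), Htra1 (0.82), Sat1 (0.72), Dcdc2a (0.68) and Ghitm (0.49). It was negative for Aoc1 (-2.53), Tns4 (-2.40), Cxcl5 (-1.56), Cdh13 (-1.08), Sept4 (-0.87), Chpf (-0.87), Cdh6 (-0.79), Akap12 (-0.57) and Sytl2 (-0.48).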

How the results depend on the processing

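The term for the replicate pair, the fits of each pair of replicates alone and the cystic disease list without Pkd2 were tests chosen only after the result was seen. Over all settings 156 values kept their call or stayed within 1.5 times and 62 did not; with single libraries left out 245 held and 11 moved. Those that did not include values from the TPM table, whose headers differ from those of the counts in DOX state, passage and replicate pair. Where another value changed the cause was not tested. Besides the list calls given beside the results, the replicate block ended the camera call of the calcium list at passage 4 (adjusted p = 0.028, then 0.059). For the difference it added cell cycle (0.022), mitochondrial DNA-encoded subunits (0.0039) and mesenchymal markers (0.030). The last were at 0.10, not called, with the replicate pair as a term. The block changed no other list call. Pkd1 averaged over passages passed with it (0.052, then 0.0059). The averaged and difference contrasts use all groups, so the compared groups alone give no separate value for them. The self-test, which held no replicate-pair effect, recovered 22% of the smallest simulated changes at the depth of these libraries, and other depths were not tested.

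The TPM headers put 8 columns under another DOX state than the counts do. By the counts, each TPM header group held 1 DOX state, 1 replicate pair and both passages. The DOX comparisons as headed therefore set replicates 3 and 4 against replicates 1 and 2. Those headed as passage set libraries with DOX against libraries without it. The TPM values below thus do not show how the results depend on processing. With TPM and a pseudocount of 1, columns as headed, genes higher and lower were 223 and 403 (DOX, passage 4), 252 and 779 (passage 7), 842 and 1623 (averaged), 477 and 798 (passage without DOX), 615 higher with DOX, and 100 and 320 at both passages. For the difference limma called 0 and 0, with 518 at an unadjusted p under 0.05 (DESeq2 142 and 203, limma-voom 80 and 95). Pkd2 was then -0.06 at passage 4 (adjusted p = 0.87) and, reversed, 0.18 at passage 7 (adjusted p = 0.42). With a pseudocount of 0.1 they were 216 and 404, 250 and 785, 824 and 1607, 478 and 792, 606 and 1601 (passage with DOX), 100 and 319, and for the difference 0 and 0 by limma, with 509 unadjusted.

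With the replicate block DOX at passage 4 gave 2143 and 2291, the difference 330 and 485 and both passages 1294 and 1467, with 5 lists higher at passage 7 and 2 lower for passage without DOX. With the replicate pair as a term these were 2135 and 2219, 339 and 482, and 1279 and 1432, with 2774 lower for passage without DOX. Replicates 1 and 2 alone gave 360 and 478 for the difference, replicates 3 and 4 alone 185 and 324.

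Camera with an estimated correlation called 1 list higher and 1 lower at passage 4, 1 and 0 at passage 7, 1 and 1 averaged, and 0 and 0 for passage without DOX (2 and 0 unadjusted). Fry called 5 and 12 at passage 7, 13 lower averaged and 11 higher for passage without DOX. Leaving out replicate 1 or 3 of passage 4 with DOX gave 45 to 95 higher and 61 to 135 lower for the difference. Lists lower ranged from 4 (without passage 7 with DOX replicate 3) to 8 averaged, and from 2 (without passage 4 without DOX replicate 1) to 4 for passage without DOX.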

Other observations

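No test in this part was chosen only after the result was seen, apart from the comparison of replicate pairs.

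Of 25 genes of calcium channels, pumps and store-operated entry 10 rose with DOX and 5 fell, averaged over passages (the same adjusted over the list alone; median 0.07), and camera did not call the list (adjusted p = 0.060). At passage 4, 9 rose and 2 fell (11 and 4 adjusted over the list alone), and camera called it higher (adjusted p = 0.028, and adjusted p = 0.12 with an estimated correlation), a call that ended with replicate number as a block (adjusted p = 0.059). Atp2a3, a calcium pump of the endoplasmic reticulum, rose by 2.01 (SE 0.13), Mcu, the mitochondrial calcium channel, by 0.43 and the calcium release channel gene Itpr2 by 0.41, while the mechanosensitive channel gene Piezo1 fell by 0.28. Of 21 chloride and fluid secretion genes 6 rose and 6 fell (the same adjusted over the list alone; camera adjusted p = 0.95): the potassium channel genes Kcnn4 (1.11) and Kcnq1 (0.78) rose, and the chloride channel gene Cftr (-0.91) and the bicarbonate transporter gene Slc4a4 (-0.54) fell. Of 17 cAMP and CREB targets 2 rose and 5 fell (3 and 5 adjusted over the list alone; median -0.08; camera adjusted p = 0.87). The growth factor gene Areg, on that list, rose by 2.06 (SE 0.20). Of 30 cilium genes 7 fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.38), with Ift172 at 0.49 and Bbs9 at -0.47.

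Camera called no cell type marker list with DOX averaged over passages, while some members passed singly. Of 9 principal cell markers 4 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.44): the sodium channel subunit genes Scnn1g (-0.96) and Scnn1b (-0.75) and the glucocorticoid-inactivating enzyme gene Hsd11b2 (-0.73) fell. Of 4 tested proximal tubule markers 3 fell, Slc27a2 (-2.27), Ggt1 (-2.10) and Cubn (-0.69). Mesenchymal markers went both ways, with Dcn (1.34) and Zeb2 (1.06) higher and the cadherin gene Cdh2 (-0.73) lower, and the list's median of -0.12 and mean of 0.10 differ in sign. At passage 4 camera called that list lower (adjusted p = 0.036, and adjusted p = 0.14 with an estimated correlation) with a median of -0.10 and a mean of 0.05.

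Zinc and iron handling genes (median 0.09) and cAMP and CREB targets (0.17) were higher as lists in replicates 3 and 4, with adjusted p = 0.042 and 0.045 with an estimated correlation. Between the replicate pairs, the clock gene Per1 (0.81) and the stress gene Ppp1r15a (0.78) were higher and Fem1b (-0.69) and Ciita (-0.92) lower in replicates 3 and 4.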
